A study of Mus musculus with 6 samples.

How the data were processed

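The series holds 6 RNA sequencing libraries of mouse primitive macrophages made from embryonic stem cells, 3 wild-type and 3 Ts1Cje, each collected after 12 days of differentiation. Libraries were made from total RNA with a SMART-seq kit, which copies full-length polyadenylated RNA. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38 for trimming, HISAT2 2.1.0 for alignment to mm10 and featureCounts 1.6.3 for counting. Whether counting used strand or reads with several positions is not given in the sources used here. The authors deposited a table of raw counts per gene and a table of TPM (abundance scaled by gene length), each with 1 column per library. The deposited TPM were the deposited counts divided by a gene length and rescaled to an equal sum in each library, which was checked on 11031 genes. No other columns per sample were in them.

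The count table has 55487 genes. Of its gene identifiers 55141 were found in GENCODE M21, 54821 with identical chromosome, start and end in mm10, and symbols were used as the table gives them. Total counts were 25484294 to 32658148 per library. Reads copied by PCR without molecular identifiers are not independent molecules, so intervals drawn from counts cover counting error only.

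Genotypes were compared on raw counts with edgeR 4.0.16 in R 4.3.3, with genotype as the only term. Genes were kept by filterByExpr with a count minimum of 10 and a total minimum of 15, libraries were scaled with TMM factors, and the quasi-likelihood test was used. Adjusted p is Benjamini-Hochberg over the 13821 genes tested, with a threshold of 0.05, and again over each gene list alone. The standard error of a log2 fold change is its size divided by the root of the F statistic. CPM are counts scaled by the library total and the TMM factor, and log2 CPM use a prior count of 2. Positive values mean higher in Ts1Cje.

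Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists cover the segment of chromosome 16 in extra copy, the genes before it, distal chromosome 12, macrophages, microglia, yolk sac progenitors, erythroid, megakaryocyte and mast, neutrophil, pluripotent, endothelial, mesenchymal, cardiomyocyte, epithelial and neural cells, interferon response, antigen presentation, inflammatory cytokines, phagocytosis, both cell cycle phases, p53, oxidative phosphorylation, antioxidants, glycolysis, cholesterol, ribosomal proteins, migration, unfolded proteins, imprinting, sex chromosomes and immediate early genes. The 25 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it on all 6 libraries. Under the other alternatives, each library left out among them, lists were tested by camera with the preset correlation alone. The interval of a list's median is a bootstrap over genes with 10000 draws at 95%, which takes genes as independent. Chromosome medians use genes with a mean log2 CPM above 1.

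The text names, first, up to 8 genes with the highest and 8 with the lowest log2 fold change among genes past the threshold with a mean log2 CPM above 1 and groups that do not overlap, which only Dnah11 met. It names, second, up to 4 tested members with the smallest p of each list described. Results of some genes that this rule names are not reported here. It names, in every case, Runx1, Erg, Ets2, Dyrk1a, Ifnar1, Ifnar2, Ifngr2, Il10rb, Rcan1, Hmgn1, Son, Sod1, Csf1r, Spi1, Kit and Xist. Any other gene was chosen after its values were seen, which is said where it appears.

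Alternatives were RLE and upper-quartile factors, TMM factors without chromosome 16, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1 and with or without a TPM minimum of 1, protein-coding genes alone, the segment by coordinate, the replicate number as a block and each library left out in turn. Tests were also run on simulated data of 13821 genes with known changes, of which 13621 were left unchanged. There edgeR recovered 1 of 68 genes changed 1.5-fold, 9 of 66 changed 2-fold and 24 of 66 changed 4-fold, with 4 false calls. DESeq2 recovered 6, 37 and 41, with 57 false calls. A set of 51 genes raised 1.5-fold passed camera, while edgeR called 0 of its members, and 4 of 100 unchanged sets had a camera p under 0.05. Simulated genes were drawn independently, while the estimated correlation of the real G2/M list was 0.98. The share of unchanged sets therefore does not show how often camera with the preset correlation errs on correlated lists.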

Results

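RNA was sequenced from primitive macrophages grown from mouse embryonic stem cells. Primitive macrophages are the first macrophages of the embryo; they arise in the yolk sac and give rise to microglia, the macrophages of the brain. The cells were made by 12 days of culture in a series of growth factors and cytokines that ended with M-CSF, the main survival factor of macrophages. The stem cells were either wild-type or Ts1Cje. Ts1Cje is a mouse model of Down syndrome that carries an extra copy of the distal segment of chromosome 16, from just beyond Sod1 to Zbtb21, joined to the end of chromosome 12. The design text asks why microglia are fewer in Ts1Cje embryos, and the comparison addresses that question at the level of RNA in their precursors. Each genotype had 3 libraries. Total counts per library were 25484294, 26293793 and 26372632 in wild-type replicates 1 to 3 and 32658148, 26146044 and 31222049 in Ts1Cje replicates 1 to 3, with 17586 to 18935 genes detected. The labels do not say whether replicates are separate stem cell lines or separate differentiations of a single line. P-values that compare libraries, such as those of single genes, therefore measure only the spread between these samples, which is possibly technical. Camera with the preset correlation compares the genes of a list with all other tested genes and takes genes as nearly independent. Its p-values therefore do not show how well a difference holds between libraries.

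The cultures had the RNA of macrophages. Csf1r, the receptor for M-CSF, averaged 1677 ± 697 CPM (counts scaled to the library total; SD, n = 3) in wild-type and 1114 ± 24.6 in Ts1Cje libraries, and Spi1, a transcription factor required for macrophages, averaged 204 ± 37.6 and 230 ± 1.54 CPM (SD, n = 3). Kit, a receptor of blood progenitors, was at 2.06 ± 2.65 and 4.88 ± 3.17 CPM (SD, n = 3). Xist, the RNA that coats an inactive X chromosome, had 4 counts in wild-type replicate 2 and 0 in the other libraries, and the Y-linked genes were transcribed in all 6. Wild-type replicate 1 stood apart from the other 5 libraries. On the first principal component, which held 37.8% of the variance, it scored -88.2, against -18.7 to 38.7 for the rest.

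Across all genes, 1 gene passed the threshold between the genotypes. Dnah11, which encodes a motor protein of motile cilia, rose in the Ts1Cje macrophages from close to none to rank 285 by mean count among all genes. Its level was 0.0539 ± 0.0934 CPM (SD, n = 3) in wild-type and 477 ± 61.4 CPM (SD, n = 3) in Ts1Cje libraries. Counts were 4, 0 and 0 in wild-type replicates 1 to 3 and 18314, 11271 and 13788 in Ts1Cje replicates 1 to 3, so that all 3 Ts1Cje libraries lay above all 3 wild-type libraries. The ratio of summed CPM was 9409, with an exact 95% interval of 3675 to 34535 that covers counting error only. The edgeR log2 fold change was 13.06 ± 0.57 (SE), with an adjusted p of 0.000426 (edgeR quasi-likelihood with Benjamini-Hochberg over 13821 genes). That fold change rests on few wild-type counts. It was 16.74 without wild-type replicate 1, which leaves 0 wild-type counts and makes the fitted value depend on the prior count, and 6.61 on log2(TPM + 1). Adjusted p ranged from 1.36e-64 with DESeq2 to 0.0558 with the replicate number as a block. Beyond Dnah11 the second smallest adjusted p was 0.792. On simulated data edgeR recovered 1 of 68 genes changed 1.5-fold, so genes that did not pass can still differ. At an unadjusted p under 0.05 there were 413 genes higher and 387 lower in Ts1Cje, 800 in all, where chance gives 691. Groups did not overlap for 882 genes higher and 790 lower, 12.1% of those tested, where chance gives 10%. DESeq2 called 56 genes, 32 up and 24 down, and limma-voom called 1. In the simulated data DESeq2 made 57 false calls, so its single calls are uncertain. Without wild-type replicate 3, edgeR called 6 genes, and with the replicate block 0, at 634 genes with an unadjusted p under 0.05.

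Genes of the segment present in 3 copies were higher together. Of the 68 genes listed for it, 51 were expressed enough to be tested, and 45 of these had a positive log2 fold change. The median was 0.63 with a 95% bootstrap interval over genes of 0.54 to 0.74, a fold of 1.55 (1.46 to 1.67), where 3 copies in place of a pair give, in proportion, a fold of 1.5 and a log2 value of 0.58. The quartiles were 0.42 and 0.82. For 32 of the 51 genes every Ts1Cje library lay above every wild-type library and for 0 every library lay below, where chance gives 10% of genes. The segment passed camera with the preset correlation (adjusted p = 8.67e-20, limma) and held with an estimated correlation (adjusted p = 0.0186) and with fry (adjusted p = 0.00572). Library medians, relative to the wild-type mean, were 0.04, -0.08 and -0.00 in wild-type and 0.67, 0.59 and 0.57 in Ts1Cje replicates 1 to 3. An exact two-sided permutation of these 6 medians gave p = 0.1, the smallest that 3 against 3 can give. Gene by gene, edgeR called 0 of the 51 over all genes tested, although 31 had an unadjusted p under 0.05; DESeq2 called 9 and limma-voom 0. Adjusted over the list alone, 26 rose and 0 fell by edgeR quasi-likelihood with Benjamini-Hochberg. That count was 4 without wild-type replicate 2, 15 without Ts1Cje replicate 1, 14 without Ts1Cje replicate 2, 15 without Ts1Cje replicate 3 and 12 with the replicate block.

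**Figure D1:**
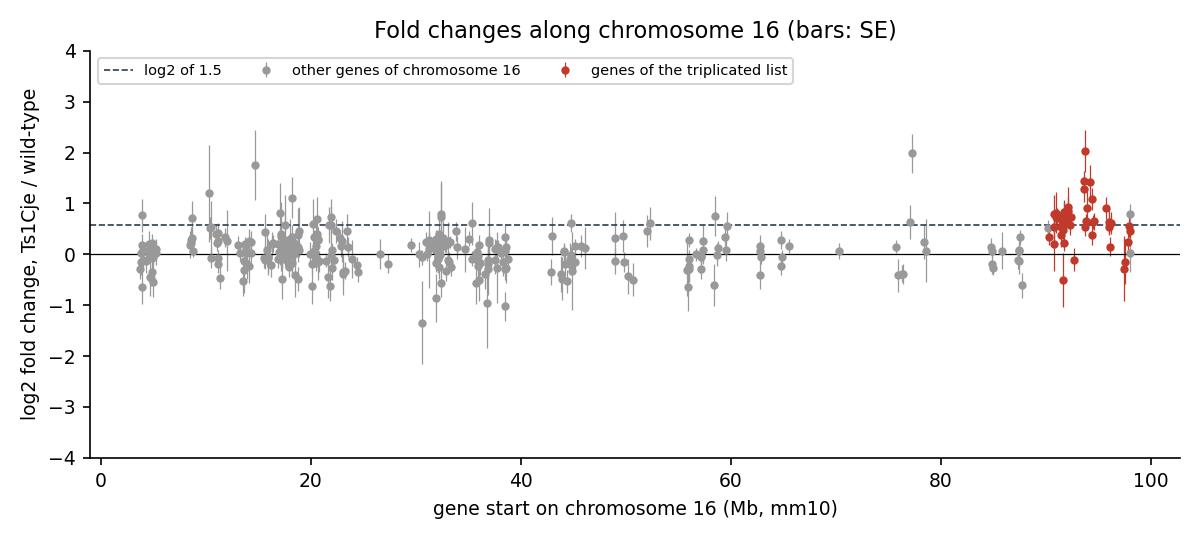
Log2 fold change (Ts1Cje over wild-type, edgeR) of expressed genes along chromosome 16 by position in megabases of mm10, with genes of the segment listed for Ts1Cje marked and a line at the log2 value of 1.5, which is 0.58. Tested genes of the segment have a median of 0.63, and those of the neighbouring list before it a median of 0.07.

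**Figure D2:**
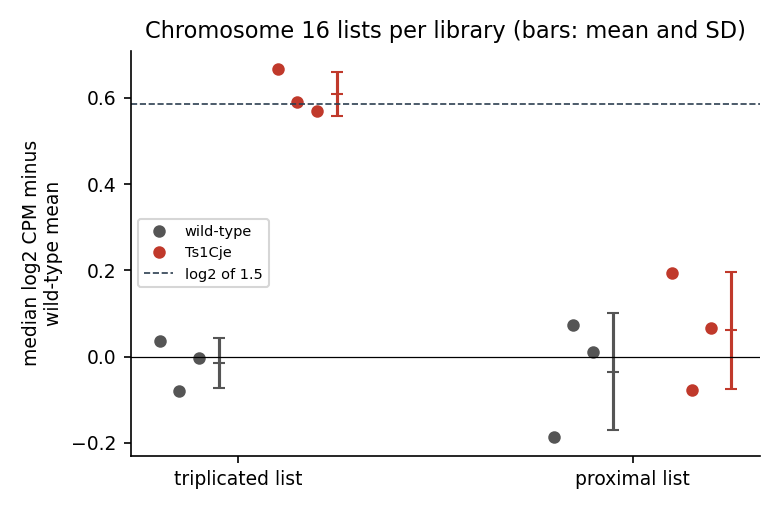
Median over genes of log2 CPM minus the wild-type mean, in each of the 6 libraries, for the segment carried in extra copy and for the neighbouring genes before it on chromosome 16. The 3 Ts1Cje libraries lie between 0.57 and 0.67 for the segment and the 3 wild-type libraries between -0.08 and 0.04.

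The 4 genes of the segment with the smallest p were Cbr1, which encodes a carbonyl reductase, Gart, an enzyme of purine synthesis, Synj1, a lipid phosphatase of endocytosis, and Ttc3, a ubiquitin ligase. Adjusted over the list alone each rose, with log2 fold changes of 1.44 ± 0.20, 0.77 ± 0.14, 0.74 ± 0.14 and 1.09 ± 0.22 (SE). The segment holds 4 receptor chains for interferons and interleukins. Of these Ifngr2, a chain of the interferon gamma receptor, went from 212 ± 24.4 to 336 ± 17.3 CPM (SD, n = 3), a log2 fold change of 0.67 ± 0.14 (SE). Ifnar1, of the type I interferon receptor, had 0.57 ± 0.15 and Il10rb, shared by receptors of the interleukin 10 family and with the highest level in the segment, 0.54 ± 0.16. These 3 rose when adjusted over the list alone. Ifnar2 did not pass, at 0.38 ± 0.23. Among regulators, Ets2, a transcription factor, had 0.91 ± 0.21, Dyrk1a, a protein kinase, 0.65 ± 0.17, Rcan1, an inhibitor of calcineurin, 0.74 ± 0.22 and Son, a splicing cofactor, 0.48 ± 0.17 (SE), and each rose when adjusted over the list alone. Over all genes tested the adjusted p of each gene named so far in this paragraph that rose was 0.792. Runx1, a transcription factor required for blood formation, was at 70.3 ± 23 CPM in wild-type and 65.3 ± 4.03 in Ts1Cje (SD, n = 3), a log2 fold change of -0.11 ± 0.23 (SE). Hmgn1, a nucleosome-binding protein, had 0.15 ± 0.18, and Erg had 4 counts in wild-type and 0 in Ts1Cje libraries and was not tested. Sod1, the cytosolic superoxide dismutase at the edge of the segment, was at 0.52 ± 0.16 (unadjusted p = 0.0127 by edgeR), and it overlaps the listed gene Scaf4 by 650 bp on the opposite strand.

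Genes of chromosome 16 that lie before the segment did not pass. Of 22 listed, 15 were tested, with a median log2 fold change of 0.07 and an adjusted p of 0.996 by camera. Edge values in this list came from Bach1, a repressor of antioxidant genes, at -0.61 ± 0.25 (SE), Nrip1, a nuclear receptor corepressor, at -0.38 ± 0.16, Cct8, a chaperonin subunit, at 0.33 ± 0.16 and Usp25, a deubiquitinase, at 0.64 ± 0.34. None passed over all genes tested or adjusted over the list alone (edgeR), while 2 had an unadjusted p under 0.05 and DESeq2 called 0.

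At the end of chromosome 12, where the segment is attached, neighbouring genes moved apart. Dnah11 (ENSMUSG00000018581) lies at 117877982 to 118199043 of chromosome 12 in mm10, on the minus strand, with 82 exons in its longest transcript. Sp4, a transcription factor gene 35889 bp beyond it, was at 5.78 ± 3.16 CPM in wild-type and 1.6 ± 0.508 in Ts1Cje libraries (SD, n = 3). Its log2 fold change was -1.85 ± 0.55 (SE), lower in 3 of 3 Ts1Cje libraries than in each wild-type library. Sp4 counts, not scaled to the library total, were 200, 189 and 58 in wild-type and 69, 28 and 50 in Ts1Cje replicates 1 to 3. Wild-type replicate 3 thus lay close to the Ts1Cje libraries, and the difference rests mainly on wild-type replicates 1 and 2. On the other side of Dnah11, Cdca7l, which encodes a partner of Myc, had 0.06 ± 0.29 and Rapgef5, an activator of small GTPases, 0.69 ± 0.49 (SE). Cdca7l overlaps Dnah11 by 725 bp on the opposite strand, so its Ts1Cje counts can hold reads of Dnah11. The Dnah11 count was 32.4, 32.6 and 32.5 times that of Cdca7l in Ts1Cje replicates 1 to 3. The Cdca7l fold change may therefore not show the level of Cdca7l itself. Over all genes tested 1 of the 4 tested genes of this list of 9 rose and 0 fell. Adjusted over the list alone Dnah11 rose and Sp4 fell, with adjusted p values of 1.23e-07 and 0.0215 (edgeR quasi-likelihood with Benjamini-Hochberg). The median over these 4 genes was 0.38 and the mean 2.99. Without wild-type replicate 1 the median was 0.04, and without wild-type replicate 3 it was 0.72.

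**Figure D3:**
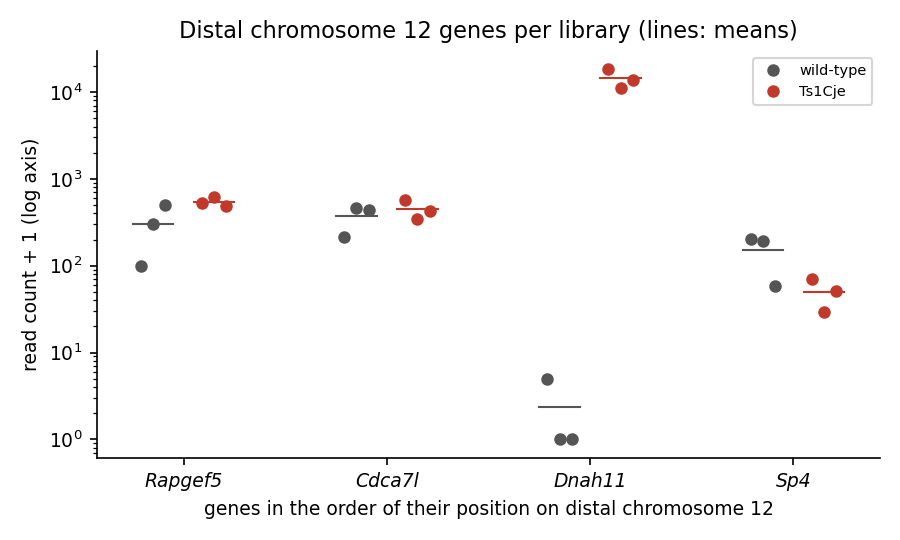
Read count plus 1, on a log axis, of tested genes at the distal end of chromosome 12 in each of the 6 libraries. Points are libraries and lines are the mean of 3. Counts are not scaled to the library total, and Sp4 has 69 in Ts1Cje replicate 1 and 58 in wild-type replicate 3. In CPM, Dnah11 averages 477 in Ts1Cje and 0.0539 in wild-type libraries, and Sp4 averages 1.6 and 5.78.

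The core macrophage genes did not pass as a list. Of 21 tested genes of the core macrophage list, 8 were positive and 13 negative, with a median of -0.05 and an adjusted p of 0.689 by camera. Mpeg1, a pore-forming protein of phagocytes, had -0.83 ± 0.32, Csf1r -0.59 ± 0.29, Cd14, a receptor for lipopolysaccharide, 0.43 ± 0.21 and Spi1 0.17 ± 0.16 (SE), and none of these 4 passed edgeR over all genes or adjusted over the list alone, with 1, Mpeg1, at an unadjusted p under 0.05 and 0 called by DESeq2. Genes enriched in microglia had a median of -0.36 over 15 tested members, 5 positive and 10 negative (adjusted p = 0.305 by camera). Those with the smallest p were the complement genes C1qa at -1.60 ± 0.55 and C1qc at -0.67 ± 0.30, Tgfbr1, a receptor for TGF-beta, at -0.43 ± 0.16 and Csf3r, the receptor for G-CSF, at -1.38 ± 0.60 (SE). None passed in edgeR over all genes or adjusted over the list alone, and 2 of the 15 had an unadjusted p under 0.05; DESeq2 called 0. The microglia list was lower without wild-type replicate 3 by camera with the preset correlation (adjusted p = 0.00866, range over the alternatives 0.00866 to 0.896). Its estimated correlation with all 6 libraries was 0.49. Genes of yolk sac progenitors had a median of -0.14 over 13 tested members (adjusted p = 0.521). Among them Meis1 had -1.13 ± 0.37, Hhex -0.26 ± 0.16, Cd93 0.53 ± 0.39, Tal1 0.30 ± 0.27 and Kit 1.25 ± 1.25 (SE). None of the list passed edgeR, 1 had an unadjusted p under 0.05 and DESeq2 called 0. Mpeg1 and Hhex lie on chromosome 19, which differed between libraries inside each genotype.

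Immune programmes were mixed. All 34 interferon response genes were tested, 18 positive and 16 negative, with a median of 0.06 and an adjusted p of 0.120 by camera. Oas1a had 0.81 ± 0.18, Oas3 1.73 ± 0.41 and Oas2 0.68 ± 0.32 (SE), all sensors of double-stranded RNA, and Bst2, which tethers budding viruses, had 0.50 ± 0.20. Oas3 averaged 36.8 ± 18.4 CPM in wild-type and 122 ± 48.5 in Ts1Cje libraries (SD, n = 3). By camera with the preset correlation the list was higher without wild-type replicate 2 (adjusted p = 2.28e-06) and without Ts1Cje replicate 3 (adjusted p = 0.0223). The range over the alternatives was 2.28e-06 to 0.896, and the estimated correlation of the list with all 6 libraries was 0.56. Antigen presentation genes had 3 positive and 11 negative values of 14 tested (median -0.22, adjusted p = 0.689), with H2-T23 at -1.21 ± 0.37, H2-Q7 at -2.19 ± 1.09, H2-DMa at 1.12 ± 0.55 and Cd74 at 0.87 ± 0.54 (SE). Inflammatory cytokine genes had 15 positive and 7 negative values of 22 tested (median 0.17, adjusted p = 0.204; 0.0383 without Ts1Cje replicate 2 and 0.0383 to 0.896 over the alternatives). Il1rn, an antagonist of interleukin 1, had 1.81 ± 0.84, Ccl12 1.54 ± 0.83, Ccl4 0.72 ± 0.40 and Csf1, which encodes M-CSF, -0.60 ± 0.31 (SE). Of phagocytosis and lysosome genes 22 were tested. Timd4, a receptor for phosphatidylserine on dying cells, rose adjusted over the list alone, from 1.08 ± 0.499 to 7.38 ± 4.31 CPM (SD, n = 3), a log2 fold change of 2.77 ± 0.58 (SE). The other members gave no common direction, and the list had a median of -0.04, a mean of 0.11 and a camera direction of up (adjusted p = 0.827). Npc1 had -0.41 ± 0.17, Msr1, a scavenger receptor, 0.59 ± 0.26 and Ctsz, a cathepsin, 0.31 ± 0.19 (SE). Genes of migration, with integrins, chemokine receptors and proteases, had a median of 0.12 over 21 tested (adjusted p = 0.565), with Itga4 at -0.50 ± 0.22, Mmp13 at 1.21 ± 0.74, Ccr1 at 0.60 ± 0.38 and Timp2 at 0.44 ± 0.31 (SE). Over all genes tested 0 genes of these 5 lists passed edgeR. At an unadjusted p under 0.05 there were 3 interferon genes, 1 antigen presentation gene, 2 phagocytosis genes and 0 of the other two lists, and DESeq2 called Oas3 and Timd4.

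Cell cycle and cholesterol genes were higher in Ts1Cje by camera with the preset correlation, but not with an estimated one (adjusted p = 0.896 for each of 3 lists). Wild-type replicate 1 had the lowest median of the 6 libraries in each list. Of 26 genes of the G1/S phase all 26 were positive, with a median of 0.40 (adjusted p = 0.000151 by camera; adjusted p = 0.896 with an estimated correlation). Ccne1, a cyclin that drives entry into S phase, had 1.45 ± 0.49, Chaf1b, a histone chaperone that also lies in the extra segment, 0.91 ± 0.39, Cdt1, a replication licensing factor, 0.55 ± 0.29 and Ung, a DNA repair enzyme, 1.08 ± 0.61 (SE). Of 24 genes of the G2/M phase 23 were positive, with a median of 0.22 (adjusted p = 0.0163; adjusted p = 0.896 with an estimated correlation), among them the mitotic kinases Cdk1 at 0.29 ± 0.34, Aurka at 0.54 ± 0.65 and Bub1 at 0.71 ± 0.88, and the cyclin Ccnb1 at 0.47 ± 0.77 (SE). All 18 tested genes of the cholesterol list were positive, with a median of 0.36 (adjusted p = 0.000974; adjusted p = 0.896 with an estimated correlation). Mvd, Nsdhl and Cyp51, enzymes of the pathway, had 0.61 ± 0.40, 0.48 ± 0.32 and 0.42 ± 0.29 (SE). Of the members 0 passed edgeR over all genes or adjusted over the list alone, where 2 G1/S genes, 0 G2/M genes and 0 cholesterol genes had an unadjusted p under 0.05 and DESeq2 called 0. Medians of the G2/M list relative to the wild-type mean were -2.0, 1.02 and 1.02 in wild-type and 1.10, 0.72 and 0.22 in Ts1Cje replicates 1 to 3. Without wild-type replicate 1 the G1/S and cholesterol lists had an adjusted p of 0.352 and 0.583 by camera with the preset correlation. The G2/M list turned to lower in Ts1Cje (adjusted p = 0.00168 by the same test). The preset correlation is 0.01, and the estimated correlation of the G2/M list with all 6 libraries was 0.98. Without Ts1Cje replicate 1 the G2/M list had an adjusted p of 0.187. List medians moved as well. Without wild-type replicate 1 they were 0.04 for G1/S, -0.27 for G2/M and 0.08 for cholesterol, and without wild-type replicate 3 they were 0.86, 0.58 and 0.71. Without Ts1Cje replicate 1 they were 0.18 for G1/S and -0.01 for G2/M, and for G2/M 0.51 without wild-type replicate 2 and 0.44 without Ts1Cje replicate 3. Over all alternatives the adjusted p ran from 1.03e-07 to 0.896 for G1/S, from 4.08e-05 to 0.896 for G2/M and from 4.62e-07 to 0.896 for cholesterol genes.

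**Figure D4:**
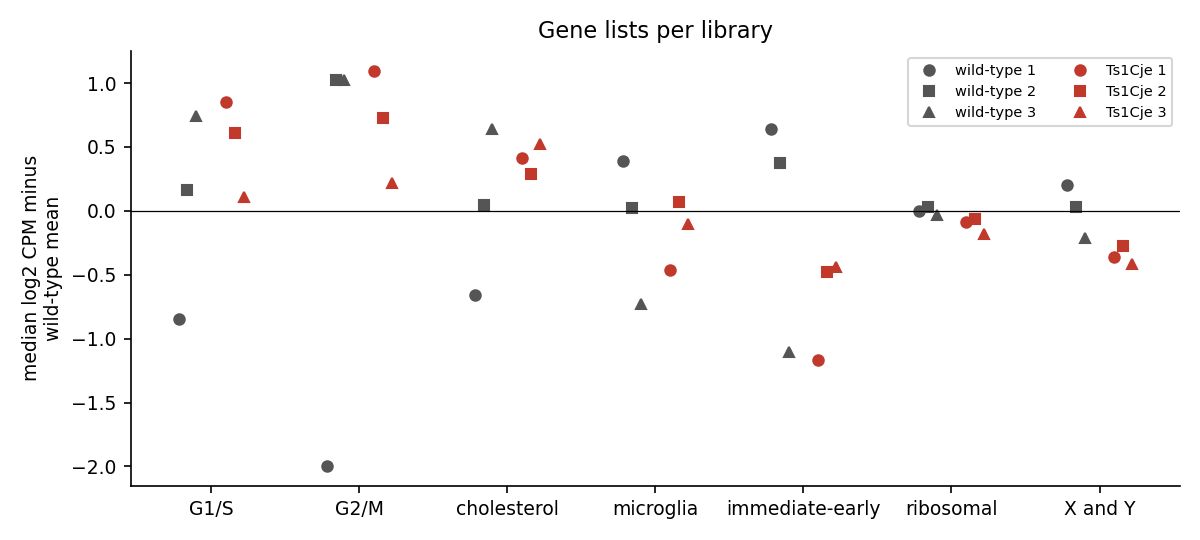
Median over tested members of log2 CPM minus the wild-type mean for selected gene lists, with a point for each of the 6 libraries. Wild-type replicate 1 lies at -2.0 for the G2/M list, where the other 5 libraries lie between 0.22 and 1.10.

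The list of X-linked and Y-linked genes, immediate early genes and ribosomal protein genes were lower by camera. The X and Y list had 8 tested members, 4 on each chromosome and all negative, with a median of -0.37 (adjusted p = 0.000569; adjusted p = 0.896 with an estimated correlation), and it stayed lower when any single library was left out. Kdm5d and Eif2s3y fell adjusted over the list alone, with log2 fold changes of -1.01 ± 0.19 and -0.85 ± 0.23 (SE), and over all genes tested 0 did, with 4 at an unadjusted p under 0.05; DESeq2 called Kdm5d (1 gene). Kdm5d, a histone demethylase on the Y chromosome, averaged 26.7 ± 2.04 CPM in wild-type and 13.2 ± 2.1 in Ts1Cje libraries (SD, n = 3). The Y-linked Uty and Ddx3y had -0.55 ± 0.19 and -0.47 ± 0.18 (SE). For all 4 Y-linked genes each Ts1Cje library lay below each wild-type library, where chance gives 10% of genes either way. The estimated correlation of the X and Y list was 0.47, so these 4 genes do not count as independent results. Relative to the mean of all 6 libraries, medians over 5 expressed Y genes were 0.55, 0.28 and 0.02 in wild-type replicates 1 to 3. In Ts1Cje replicates 1 to 3 they were -0.44, -0.14 and -0.34. Immediate early and stress genes had 15 negative values of 17 (median -0.70, adjusted p = 0.00684; adjusted p = 0.896 with an estimated correlation). Ier2 averaged 83.8 ± 51 CPM in wild-type and 20.6 ± 3.16 in Ts1Cje libraries (SD, n = 3), a log2 fold change of -2.03 ± 0.52 (SE). The transcription factors Egr1 and Fos had -1.99 ± 0.61 and -1.10 ± 0.45, and Dusp1, a phosphatase of MAP kinases, had -0.80 ± 0.30 (SE). Wild-type replicate 3 did not share the level of its group, with a median of -1.10 against 0.64 and 0.37 in wild-type replicates 1 and 2. The list had an adjusted p of 0.326 and a median of -0.36 without wild-type replicate 1, and an adjusted p of 0.0888 without Ts1Cje replicate 1, with a range of 5.36e-06 to 0.896 over the alternatives. DESeq2 called Ier2 and Egr1. Ribosomal protein genes had 26 negative values of 30 (median -0.11, adjusted p = 0.0163; adjusted p = 0.896 with an estimated correlation), with Rpl7 at -0.32 ± 0.15, Rps19 at -0.25 ± 0.13, Rpl3 at -0.31 ± 0.16 and Rpsa at -0.22 ± 0.13 (SE). Their adjusted p was 0.0964 without wild-type replicate 2, 0.0665 without wild-type replicate 3, 0.0888 without Ts1Cje replicate 1, 0.167 without Ts1Cje replicate 3 and 0.0604 with the replicate block, with a range of 0.0132 to 0.896 over the alternatives.

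Genes of stress and metabolism did not pass as lists. Genes of p53 and apoptosis had 11 positive and 12 negative values of 23 (median -0.12, adjusted p = 0.613 by camera). Lower values were seen for Trp53inp1 at -0.97 ± 0.33, Bcl2l11, which encodes the death inducer Bim, at -1.17 ± 0.42 and Fas, a death receptor gene on chromosome 19, at -1.67 ± 0.66, and Trp53 had 0.24 ± 0.13 (SE). Genes of oxidative phosphorylation were positive for 19 of 26 (median 0.06, adjusted p = 0.0889; 0.0185 without wild-type replicate 3 and 0.0185 to 0.896 over the alternatives), with Cox5a at 0.48 ± 0.15, Atp5g1 at 0.37 ± 0.17, Cox4i1 at 0.37 ± 0.19 and Cycs at 0.47 ± 0.25 (SE). Antioxidant genes were positive for 16 of 20 (median 0.26, adjusted p = 0.0889; 0.00535 without wild-type replicate 3 and 0.00535 to 0.896 over the alternatives). Prdx1, a peroxidase, had 0.45 ± 0.20 and Hmox1, the haem oxygenase repressed by Bach1, had 0.91 ± 0.40 (SE). Genes of glycolysis and hypoxia were negative for 17 of 22 (median -0.22, adjusted p = 0.114 by camera). Without wild-type replicate 1 that adjusted p was 1.64e-05 by camera with the preset correlation, with 1.64e-05 to 0.896 over the alternatives. The estimated correlation of the list with all 6 libraries was 0.46. The hypoxia targets Egln3 and Vegfa had -2.88 ± 0.86 and -1.56 ± 0.56, Pdk1 had -0.39 ± 0.17 and Gapdh, a gene with many near-identical pseudogenes and only 8.50 ± 2.61 CPM in wild-type (SD, n = 3), had -0.76 ± 0.32 (SE). Genes of the unfolded protein response had a median of -0.06 and a mean of -0.17 while camera gave the direction up (adjusted p = 0.565; 0.00572 without wild-type replicate 2 and 0.00572 to 0.902 over the alternatives), with Calr at 0.57 ± 0.28, Sdf2l1 at 0.41 ± 0.27, Creld2 at 0.30 ± 0.22 and Atf4 at -0.51 ± 0.39 (SE). Imprinted genes had a median of -0.04, a mean of 0.02 and a camera direction of up (adjusted p = 0.827), with Sgce at -0.70 ± 0.17, Ndn at 1.82 ± 0.63, Cdkn1c at 0.87 ± 0.63 and Impact at 0.19 ± 0.16 (SE). In these 6 lists 0 genes passed edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 3 p53 and apoptosis genes, 1 of oxidative phosphorylation, 2 antioxidant, 4 glycolysis and hypoxia, 0 unfolded protein and 2 imprinted genes, and DESeq2 called Egln3.

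Of the 9 lists of markers of other cell types that such cultures can hold, 6 had too few expressed members to test as lists. Levels of single members ranged widely, with Tfrc, the transferrin receptor, at 465 ± 38.2 and 577 ± 311 CPM in wild-type and Ts1Cje, Pf4, a platelet chemokine, at 100.4 ± 77.2 and 87.9 ± 51.4 and Nes, an intermediate filament gene, at 42.0 ± 16.4 and 38.7 ± 29.4 (SD, n = 3). Of the erythroid list 4 of 16 genes were tested, with Hba-a1 at -1.83 ± 1.47, Hba-x at -0.83 ± 1.57, Epor at -0.16 ± 0.34 and Tfrc at 0.31 ± 0.34 (SE). Of megakaryocyte and mast cell genes 4 of 17 were tested, and Itgb3, an integrin subunit also made by macrophages, rose adjusted over the list alone, from 160 ± 72.3 to 326 ± 45.2 CPM (SD, n = 3). Over all genes tested its adjusted p was 0.792 (edgeR), and DESeq2 called 0 genes of this list. Pf4, Vwf and Ppbp had -0.19 ± 0.62, -0.24 ± 0.79 and -2.13 ± 1.02 (SE). A single neutrophil granule gene, Mmp8 (0.78 ± 1.32, SE), and a single pluripotency gene, Klf4 (-0.48 ± 0.76, SE), were tested, and of 10 neural genes Map2 (3.11 ± 1.33) and Nes (-0.12 ± 0.52). Endothelial genes had a median of -0.47 over 9 tested (adjusted p = 0.844 by camera), with Eng at -1.08 ± 0.41, Pecam1 at -0.99 ± 0.58, Kdr at 0.97 ± 0.48 and Flt1 at 0.86 ± 0.74 (SE). Mesenchymal genes had a median of 0.69 over 7 tested (adjusted p = 0.355), with Dcn at 1.24 ± 0.60, Fn1 at 0.69 ± 0.52, Col1a1 at 0.99 ± 0.83 and Acta2, on chromosome 19, at 0.85 ± 0.70 (SE). All 4 tested cardiomyocyte genes were negative, with Myh6 at -2.23 ± 1.73, Actc1 at -2.43 ± 1.68, Tnnt2 at -1.36 ± 1.12 and Myl4 at -1.13 ± 1.30 (SE). Myh6, the heavy chain of heart myosin, had 1119 counts in wild-type replicate 1, 43 and 18 in wild-type replicates 2 and 3, and 6, 249 and 21 in Ts1Cje replicates 1 to 3. Epithelial and endoderm genes passed camera as higher (adjusted p = 0.0144; adjusted p = 0.896 with an estimated correlation), with 5 positive and 5 negative values, a median of 0.05 and a mean of 0.31. Sox7, a factor of endoderm and of early blood vessels, had 2.71 ± 0.78, Ttr 1.95 ± 1.37, Cdh1 -1.20 ± 1.84 and Cldn6 -1.25 ± 1.92 (SE). Of the 10 tested members 6, Cdh1 and Cldn6 among them, had 0 counts in wild-type replicates 2 and 3. The median of the list was 6.70 without wild-type replicate 1, which is no bound since it rests on such genes. It was -0.43 and -0.50 without wild-type replicates 2 and 3, and 0.30, 0.03 and 0.29 without Ts1Cje replicates 1 to 3. The list had an adjusted p of 0.247 without wild-type replicate 2 and of 0.284 without wild-type replicate 3, with a range of 4.63e-13 to 0.896 over the alternatives. DESeq2 called Sox7.

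On chromosome 19 libraries differed inside each genotype. Medians of the log2 fold change over expressed genes were 0.08 for chromosome 16, -0.09 for chromosome 19, -0.04 to 0.08 for the other autosomes and -0.06 for the X chromosome. The median was -0.55 over 5 genes of the Y chromosome and -0.21 over 13 mitochondrial genes. Relative to the mean of all 6 libraries, the median of the 400 expressed genes of chromosome 19 was -0.14, -0.00 and 0.28 in wild-type replicates 1 to 3 and -0.19, 0.12 and -0.01 in Ts1Cje replicates 1 to 3. That is a range of 0.47 between libraries, where the other autosomes had ranges of 0.02 to 0.18. The difference lies inside both genotypes and does not follow them.

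**Figure D5:**
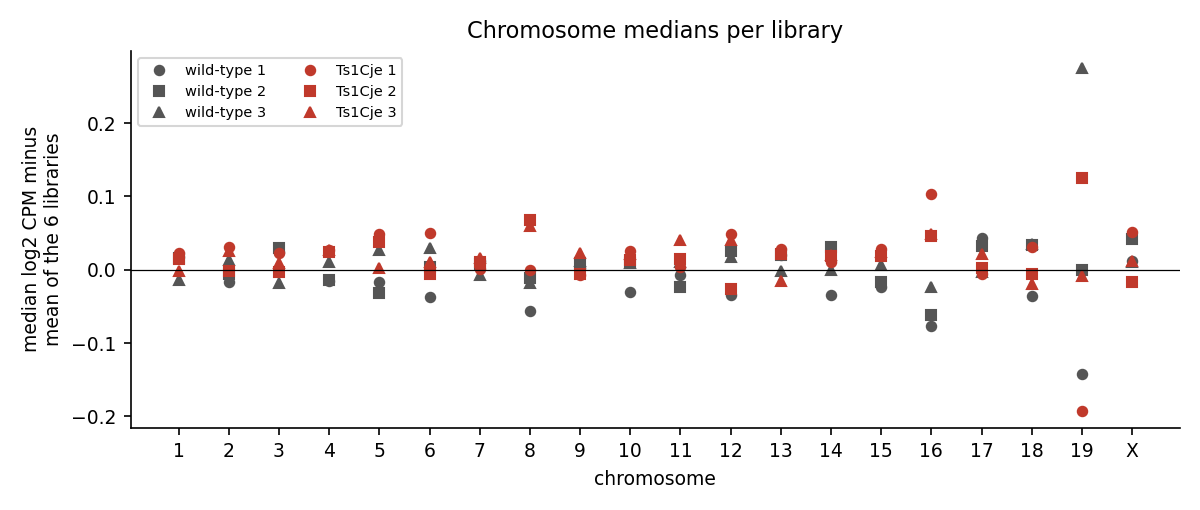
Median over expressed genes of log2 CPM minus the mean of all 6 libraries, for each autosome and the X chromosome in each library. The Y chromosome (5 genes) and mitochondrial genes (13) are not drawn and had wider ranges between libraries, 0.99 and 0.57, than chromosome 19 at 0.47. On chromosome 19 wild-type replicate 3 lies at 0.28 and Ts1Cje replicate 1 at -0.19.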

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

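DESeq2 on all genes, robust edgeR, the other scalings and the correction for GC content and length of chromosome 19, the term tests and the list medians with a library left out were chosen after the results were seen; the other alternatives were not. The median of the chromosome 16 segment stayed between 0.52 and 0.65 under all 21 alternatives and passed camera wherever that was computed. The range of chromosome 19 between libraries stayed between 0.46 and 0.48. The count of genes changed, 1 as reported, was 3 with no filter (Dnah11, Mfge8 and Cbr1), 56 with DESeq2, 44 with DESeq2 on all genes, 0 with the replicate block and 1 to 6 with a library left out, the 6 without wild-type replicate 3. Segment genes past the threshold, 0 as reported, were 1 with no filter, 9 with DESeq2 and 5 with DESeq2 on all genes. Adjusted over the list alone they were 26 as reported, 12 with the replicate block and 4 to 24 with a library left out, the 4 without wild-type replicate 2. The distal chromosome 12 median, 0.38 as reported, was 0.0773 on log2(TPM + 1) with no filter and 0.0369 to 0.717 with a library left out. Lists past the threshold, 8 as reported, were 1 with an estimated correlation, 1 with fry and 5 to 9 with a library left out, the 5 without Ts1Cje replicate 1. The G2/M cell cycle list was reversed without wild-type replicate 1, with an adjusted p of 0.00168 by camera with the preset correlation. With a library left out that adjusted p ranged from 4.08e-05 to 0.187. The cause was not tested. Of 2867 values of 145 named genes, 2828 stayed on their side of the threshold, 58 of them with the other sign in genes not called. Another 38 became stronger and 1 weaker, Dnah11 with the replicate block (adjusted p = 0.0558, edgeR). Only Dnah11 was past the threshold as reported. For the other named genes, staying on their side means no call again, which does not show that their fold changes are stable. Replicate numbers showed no pairing of the samples: deviations of replicates with equal number correlated across genes, which are not independent, at -0.18, -0.05 and -0.06. The largest shift of the median of all genes by a scaling was -0.03, with upper-quartile factors. In simulated data with the number of libraries used here edgeR recovered 1 of 68 genes changed 1.5-fold.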

Other observations

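Tests in this part chosen after the results were seen are those of cilia genes, Cdca7l, Sp4, the GC content and length correction, bins and copies of chromosome 19, wild-type replicate 1, the genotype in the cell cycle and cholesterol lists, the splits counted with edgeR and the term tests. Genes named in this and the next paragraph were chosen after their values were seen. Mfge8, a secreted protein that bridges dying cells to phagocytes, averaged 94.3 ± 4.89 CPM in wild-type and 353 ± 149 in Ts1Cje libraries (SD, n = 3), a log2 fold change of 1.90 ± 0.29 (SE). It was past the threshold with no filter (adjusted p = 0.0114, edgeR) and with DESeq2 (adjusted p = 3.74e-06), and its adjusted p was 0.792 as reported. Tyro3, a receptor kinase for ligands bound to phosphatidylserine, had 0, 0 and 2 counts in wild-type and 42, 24 and 49 in Ts1Cje replicates 1 to 3. Its relatives Axl and Mertk had log2 fold changes of -0.46 ± 0.59 and -0.55 ± 0.35, and their ligand Gas6 had 0.28 ± 0.26 (SE). Cd33, an inhibitory receptor for sialic acid, averaged 28.4 ± 12.2 and 77.1 ± 10.4 CPM (SD, n = 3), and the scavenger receptors Stab1 and Cd36 had -0.04 ± 0.42 and 0.07 ± 0.34 (SE).

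Among lower genes, Ighm, the heavy chain of immunoglobulin M, averaged 82.5 ± 47.5 CPM in wild-type and 14.5 ± 6.79 in Ts1Cje libraries (SD, n = 3), and Tmem88, a membrane protein that restrains Wnt signalling, 15.1 ± 2.25 and 3.79 ± 1.6. Their log2 fold changes were -2.51 ± 0.53 and -2.0 ± 0.36 (SE), past the threshold with DESeq2 (adjusted p = 0.000700 and 0.000575). Calls by DESeq2 alone are uncertain, since it made 57 false calls in the simulated data. In the extra segment Cbr3, the neighbour of Cbr1, had 2.03 ± 0.42 (SE), while the interferon-induced Mx1 and Mx2 had -0.28 ± 0.64 and -0.15 ± 0.44. Mir99ahg, a non-coding RNA gene of chromosome 16 outside the listed segment, averaged 2.90 ± 1.49 and 11.4 ± 1.90 CPM (SD, n = 3). Of 896 process terms named with the counts, none passed camera (limma), and the smallest adjusted p was 0.502, shared by several terms.

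Dnah11 RNA appeared in all 3 Ts1Cje libraries. Ciliated cells in the cultures are argued against by the other genes of motile cilia: of 23 listed, the highest, Rsph1, reached 6.59% of Dnah11 in TPM, with 6.49 in Ts1Cje and 4.21 in wild-type libraries, and Foxj1, Dnah5 and Tekt1 had 0 counts in Ts1Cje. Reads of the overlapping Cdca7l are argued against by a Dnah11 count at least 32.4 times that of Cdca7l in each Ts1Cje library and 0.0187 times or less in wild-type. A hypothesis that stays open is a transcript made across the rearranged chromosome of Ts1Cje. Counts per gene hold no reads across junctions, so they cannot show it. Sp4 was lower (log2 fold change -1.85). The list of distal chromosome 12 was fixed because the Ts1Cje translocation is known to have lost some genes there. Whether such a loss or such a transcript accounts for less Sp4 cannot be told from these counts.

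Chromosome 19 differed between libraries, most between wild-type replicate 3 and Ts1Cje replicate 1. A bias of GC content or length is argued against by a gap of 0.46 after correction for both, against 0.47 before. A few strongly changed genes are argued against by the smallest gap of 6 position bins, 0.34. Whether cultures differ in copies of chromosome 19 stays open: 89.8% of its genes were higher in wild-type replicate 3 than in Ts1Cje replicate 1, but these libraries were picked as the highest and lowest, so the share restates their gap and adds no support. No biological explanation by genotype was tested, since both libraries differ from others of their own group.

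Cell cycle and cholesterol genes were higher in Ts1Cje as lists by camera with the preset correlation, but the smallest adjusted p of the 3 lists with an estimated correlation was 0.896. Without wild-type replicate 1 the G2/M list turned to lower (adjusted p = 0.00168 by camera with the preset correlation). The median over the 68 members was 0.317 with that library and -0.0193 without it. This library was picked as the one with the lowest median in each of the 3 lists. Leaving it out therefore raises the wild-type level, so the fall restates that choice and adds no support. Whether wild-type replicate 1 alone accounts for the higher lists stays open. A role of genotype cannot be told apart from that of this library with 3 libraries a group that differ among themselves.

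The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The numbers of splits given here include the real split and any split with more calls. In 2 of the 10 splits edgeR called as many genes as in the real one, which called 1, and the highest other called 1. With DESeq2 3 splits called as many as the real 56, and the highest other called 238, with wild-type replicates 1 and 2 and Ts1Cje replicate 3 on a side; a count several times the real one points to a structure of the samples other than genotype. For segment genes adjusted over the list alone 1 split, the real one, gave 26, and the highest other gave 0. For lists past camera 7 splits gave as many as the real 8, and the highest other gave 13.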
